A study of Equus caballus with 8 samples.

How the data were processed

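Horse placental tissues and lymphocytes were profiled on one-colour Agilent horse arrays, with 1 sample per array. RNA was amplified and labelled with Cy3, per the labels' protocols. The spot intensities that the authors deposited for each array are background-subtracted signals on a linear scale, with no normalization between arrays. They came from Agilent Feature Extraction 10.5.1.1, per the file headers, while the submitters' processing notes name Agilent Feature Extraction 9.1. Intensities of the array for the girdle of conceptus 3879, carry 3 significant digits in the file that the authors deposited. The authors also deposited a table for each comparison, with log2 values centred per probe, a fold change without sign (a ratio) and a direction word. The table for girdle and chorion also holds an uncorrected p-value per probe, and lists probes with a p-value of at most 0.05. How the authors made these tables is not given in the sources used here. The p-values of the authors' deposited table matched a paired t-test on quantile-normalized signals computed here (Spearman correlation 0.99993 across 14550 probes, and 99.8% of p-values within 10%).

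Samples were grouped by the labels as chorionic girdle, chorion, resting lymphocytes and stimulated lymphocytes. Girdle and chorion of 1 conceptus share its number in the labels, and the series' design compares matching tissues, so the conceptus was used as a block. This pairing was checked by correlating the deviations of each array from its tissue mean. Arrays of the same conceptus correlated at 0.56, 0.80 and 0.51, and arrays of different conceptuses at -0.65 to 0.37, so that every array correlated best with its own conceptus. Conceptus 3879 lay alone on its slide, so its values cannot tell the pairing from the slide. Between conceptuses 3637 and 3961, on the same slide, the correlations were 0.23 and 0.37. Conceptuses 3637 and 3961 shared 1 slide, conceptus 3879 lay on a second slide and the lymphocytes on the third. Scanner ceilings were 65511 on the first slide and 778448 on that of conceptus 3879, and 5.91% to 7.35% of probes were saturated on the 4 arrays of the first slide, against 0 on the other arrays.

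Of 45220 spots per array, 43803 were not controls. Signals of spots of 1 probe were averaged (50 probes had 5 spots each) after 72 spots marked as population outliers over all arrays were dropped. Saturated spots were kept. The main values are the log2 of the processed signal minus the 75th percentile of the array. The SD of log2 signals over the 5 spots of such probes was 0.069 to 0.091, which covers technical spread within an array only. The correlation of these values across probes was 0.948 to 0.984 between arrays of 1 placental tissue, 0.941 to 0.944 between the tissues of 1 conceptus and 0.938 between the lymphocyte arrays.

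For girdle against chorion, a probe was tested if it was well above background on all 3 arrays of at least 1 tissue, which left out 8078 probes, and had a value and no mark as non-uniform on all 6 arrays, which left out 230 more. The 35295 probes tested covered 20386 transcript identifiers. Linear models with conceptus and tissue were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. The model was tested on simulated arrays with the spread of the 35295 probes, of which 200 were changed. It recovered 0% of probes changed 1.5-fold, 4% at 2-fold, 86% at 4-fold and 92% at 8-fold, and called 9 unchanged probes. The real arrays held more probes past the threshold, for which the adjustment is less strict. Resting and stimulated lymphocytes were compared by the difference of the 2 arrays, with no test. A probe not well above background on any array of a group was given a bound, from the mean of the brighter group and, per array of the dimmer one, the higher of its own signal and the lowest signal well above background. Tables were read with the R packages data.table (version 1.17.8) and jsonlite (version 2.0.0), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

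The files give a probe name and an accession (Ensembl transcript for 74.2% of probes, GenBank or EST for 16.5%, RefSeq for 9.33%) and do not pair them with gene names. The rule fixed before the data were examined named genes by symbol: for girdle against chorion those with the highest and lowest log2 difference among genes past the threshold, with 1 sign in all 3 conceptuses and well above background on all 6 arrays, and for lymphocytes those with the highest and lowest difference among genes well above background on both arrays. It counted identifiers without a symbol and named none. As every identifier lacked a symbol, the 2 highest and the 2 lowest transcripts by each ranking are named by accession, a choice made after the files had been seen. A transcript with several probes is represented by the brightest. The genes that the rule would have named whatever their values, and the 35 gene lists fixed in advance, were not analysed here, because their members are symbols.

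Alternatives fixed before the data were examined were the fit without the conceptus as a block, quantile and median scaling, other filters on dim probes, another prior of the variance (with a trend or robust), the slide as a block, leaving out each conceptus, plain t-tests, a fold minimum, 1 probe per transcript and the deposited tables. Added after the files had been seen were normexp background correction (offset 50) on median spot and background signals, leaving out saturated probes, capping signals at the lower scanner ceiling, keeping probes marked as non-uniform, and counting probes called in 1 direction under all 3 scalings.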

Results

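Gene expression was measured in horse placental tissues and blood lymphocytes on 8 one-colour oligonucleotide arrays, each hybridised with Cy3-labelled RNA of 1 sample. Chorionic girdle and chorion had been dissected from 3 conceptuses recovered on days 33, 34 and 35 of gestation, which gave 3 arrays per tissue. The chorionic girdle is the band of invasive trophoblast that forms the gonadotropin-secreting endometrial cups, and the chorion is non-invasive trophoblast. The other 2 arrays held lymphocytes of 1 mare, either resting or stimulated with pokeweed mitogen, a plant lectin that drives lymphocytes to divide. The RNA of the stimulated cells was a pool of cells harvested over several days of culture. Each array carried 43603 probes for 24417 transcript identifiers, and 77.1% to 89.3% of the probes were well above background on each placental array. The corresponding shares were 81.8% in resting and 80.4% in stimulated lymphocytes. The number of arrays limits the precision of each value. The files do not pair the identifiers with gene names, so transcripts are given by identifier. Levels are log2 signals relative to the 75th percentile of the array.

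The first comparison asked which transcripts differed between the invasive trophoblast of the girdle and the chorion of the same conceptus. Transcript ENSECAT00000019851 was 170-fold higher in the girdle (log2 difference 7.41, SE 0.14, limma adjusted p = 0.00203). Its level was 0.85 ± 0.47 in girdle and -6.56 ± 0.43 in chorion (SD, n = 3). It was higher in the girdle of all 3 conceptuses, but 1 sign in all 3 was a condition for naming a transcript. Transcript DN507748 was 145-fold higher in the girdle (log2 difference 7.18, SE 0.31, limma adjusted p = 0.00203), at 2.27 ± 0.39 in girdle and -4.91 ± 0.41 in chorion (SD, n = 3). Its probe was saturated on 1 of the 3 girdle arrays. Transcript EF379126 was 97.9-fold lower in the girdle (log2 difference -6.61, SE 0.14, limma adjusted p = 0.00203), at -6.34 ± 1.09 in girdle and 0.28 ± 1.24 in chorion (SD, n = 3). All 5 of its probes passed the threshold in that direction, with log2 differences of -6.88 to -6.49. Transcript DN508408 was 222-fold lower in the girdle (log2 difference -7.79, SE 0.87, limma adjusted p = 0.00599), at -5.24 ± 2.79 in girdle and 2.55 ± 0.64 in chorion (SD, n = 3). Its difference was -6.48 in conceptus 3637, -6.60 in conceptus 3879 and -10.31 in conceptus 3961, and without conceptus 3961 the fitted difference was -6.54. In the girdle of conceptus 3961 its signal was 29.7, against 850 and 787 in the other girdles. That is near the lowest signal well above background on that array (19.4). All 5 of its probes were lower in the girdle, with log2 differences of -7.91 to -7.79. With normexp background correction these differences shrank to 6.08 for ENSECAT00000019851, 6.57 for DN507748, -5.84 for EF379126 and -7.17 for DN508408.

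**Figure D1:**
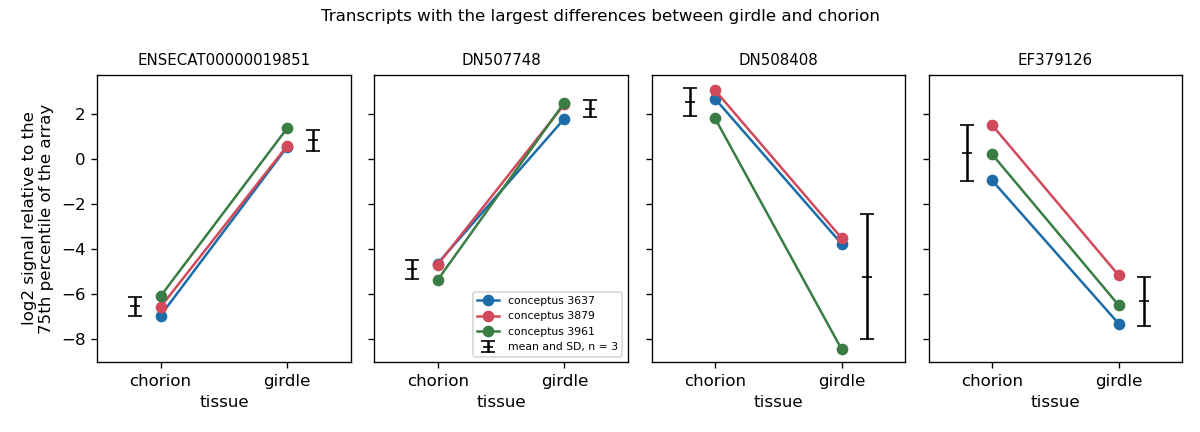
Log2 signal relative to the 75th percentile of the array (vertical axis) in chorion and girdle (horizontal axis) for the 4 named transcripts. Each coloured line joins the 2 tissues of 1 conceptus, and black bars give the mean and SD of 3 arrays, with the girdle of conceptus 3961 well under the others for DN508408.

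Differences between the tissues were widespread, most of them smaller than those of the named transcripts. Of 35295 probes tested, 11806 (33.4%) differed between the tissues in the same direction under each of 3 scalings of the arrays (limma, adjusted p under 0.05), 5940 higher and 5866 lower in the girdle. Counted by the brightest probe of each transcript, 3291 transcripts were higher and 3207 lower. Among these probes, and by that much under each of the 3 scalings, 1223 were at least 4-fold higher and 2214 at least 4-fold lower in the girdle, and 265 were at least 16-fold higher and 192 at least 16-fold lower. With scaling to the 75th percentile alone, 14203 probes passed the threshold, of which 6117 (43.1%) were higher and 8086 (56.9%) lower in the girdle. This split turned with the scaling. The share higher was 54.9% under quantile normalization (7958 higher and 6547 lower) and 60.8% under scaling to the median (9768 higher and 6309 lower). Quantile normalization shifted the differences of all tested probes by a median of 0.16 on the log2 scale towards the girdle, and scaling to the median by 0.23. Of all tested probes, 72.4% had the same sign in the 3 conceptuses, against 25% by chance. The median size of the difference among the 14203 probes was 2.39-fold, and the smallest log2 difference that passed was 0.44.

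**Figure D2:**
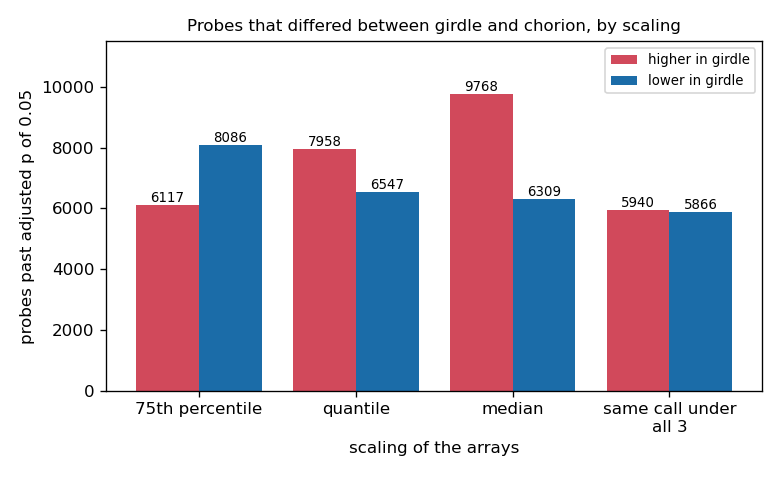
Number of probes past an adjusted p of 0.05 (vertical axis, from 0) that were higher or lower in girdle than in chorion, for each scaling of the 6 arrays (horizontal axis). Lower probes outnumbered higher ones with the 75th percentile (8086 against 6117), higher probes did so with quantile and median scaling, and the calls shared by all 3 scalings were nearly even (5940 and 5866).

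Some transcripts were well above background in 1 tissue only. Picking probes in this way favours a difference, and 40.2% of all tested probes passed the threshold. On all 3 girdle arrays and no chorion array, 101 probes were detected, and 96 of them passed the threshold. A lower bound could be set for 95 of these, with a median of at least 4.31-fold and a maximum of at least 260-fold higher in the girdle. On all 3 chorion arrays and no girdle array, 159 probes were detected, and 156 of them passed the threshold. Their bounds had a median of at least 3.82-fold and a maximum of at least 65.9-fold lower in the girdle. Such a bound sets the mean of the bright tissue against the mean of the other, where each array of the other tissue enters with the higher of the probe's own signal and the lowest signal counted as well above background. Probes of 1 transcript mostly shared a sign. Of 3178 transcripts with 2 or more tested probes and at least 1 past the threshold, 3034 (95.5%) had a single sign across their probes. In 2161 (68.0%) all probes passed in 1 direction, and 20 had probes that passed in both directions. Among the probes called under all 3 scalings, 53.5% of 8977 probes for Ensembl transcripts were higher in the girdle, against 39.3% of 2021 for GenBank or EST accessions and 41.8% of 808 for RefSeq transcripts. The Ensembl share was the highest of the 3 classes under each scaling, although every class had more lower than higher probes with the 75th percentile and more higher than lower with the median.

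The arrays of conceptuses 3637 and 3961 lay on 1 slide and those of conceptus 3879 on another, and both slides held both tissues. Arrays of 1 tissue on the same slide differed by at least 2-fold at 10.1% (chorion) or 12.1% (girdle) of probes. Across slides, arrays of 1 tissue differed by that much at 31.0% to 32.5% of probes, which lies within the range of girdle against chorion within a conceptus (29.6% to 33.2%). These shares include probes dim on 1 array of a pair. Among probes well above background on both arrays, the share was 29.0% to 31.5% across slides. Between the tissues of 1 conceptus it was lower, at 26.8% to 28.7%. With the slide as a block in place of the conceptus, 13859 probes passed the threshold. Within the slide of conceptuses 3637 and 3961 alone, 6054 probes passed, and 97.8% of them had the same direction in conceptus 3879. Over the 35295 tested probes, 83.1% had the same direction on both slides (r = 0.88 across probes, which are not independent replicates). The slide of conceptus 3879 held 1 array per tissue, so no test was made within it. The count was 7841 without conceptus 3637, 6054 without conceptus 3879, 9315 without conceptus 3961 and 6122 without the conceptus as a block. A plain paired test, which estimates the spread of each probe from its own 3 pairs, left 3 probes after Benjamini-Hochberg adjustment, none of the named transcripts among them, and 13995 at an unadjusted p under 0.05.

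**Figure D3:**
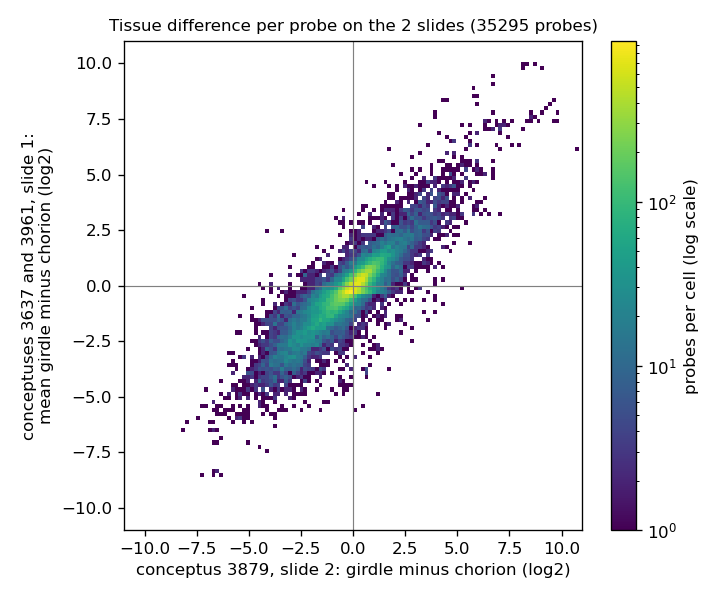
Girdle minus chorion in log2 for each of 35295 probes in conceptus 3879 (horizontal axis) and as the mean of conceptuses 3637 and 3961 (vertical axis), with colour giving the number of probes per cell on a log scale. Most probes lie near a rising line, and 83.1% of probes have the same direction on both slides.

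The authors' deposited table for this comparison lists 14550 probes with an uncorrected p of at most 0.05, of which 8555 are marked higher and 5995 lower in the girdle. Of its probes, 13701 were tested here and 10588 passed the threshold, all of them in the direction given in the authors' deposited table. Both come from the same arrays, so the shared directions are no independent check.

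The second comparison asked how transcripts of lymphocytes stimulated with mitogen differed from those of resting ones. It rested on 1 array per state from 1 mare, so the differences have no replicate check, no test was made, and they describe these 2 arrays. The stimulated cells were a pool over several days of culture. With only these 2 arrays, an effect of the mitogen cannot be told apart from one of the time in culture. Transcript DN504495 was 1347-fold higher in stimulated cells (log2 difference 10.40), with a signal of 100078 against 66.5 in resting cells. Transcript NM_001082519 was 544-fold higher (log2 difference 9.09). Its 2 probes well above background on both arrays gave log2 differences of 9.09 and 9.39. Its other 15 probes were well above background in stimulated cells only, at bounds of at least 559-fold to at least 756-fold higher. Transcript ENSECAT00000009966 was 2040-fold lower in stimulated cells (log2 difference -10.99), and all 5 of its probes were lower. This transcript was also lower in girdle than in chorion (log2 difference -5.94, limma adjusted p = 0.00203), although it was well above background on only 2 of the 3 girdle arrays. Transcript ENSECAT00000000831 was 1374-fold lower in stimulated cells (log2 difference -10.42). With normexp background correction the 4 log2 differences were 9.22 for DN504495, 8.07 for NM_001082519, -10.07 for ENSECAT00000009966 and -9.72 for ENSECAT00000000831.

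Of 36688 probes well above background on at least 1 of the 2 arrays, 11891 (32.4%) differed by at least 2-fold, 5766 higher and 6125 lower in stimulated cells. At least 4-fold differences were found at 2208 probes that were higher and 2281 that were lower, and at least 16-fold differences at 497 and 529. These counts take probes that were dim on 1 array at their measured signal there. With normexp background correction, 1507 probes were at least 4-fold higher and 1516 at least 4-fold lower. Over the 33925 probes well above background on both arrays, 9841 (29.0%) differed by at least 2-fold, with 1557 at least 4-fold higher and 1482 at least 4-fold lower. A further 1076 probes were well above background in stimulated cells only, at a median of at least 3.01-fold higher, and 438 of them were at least 4-fold higher. Another 1687 were well above background in resting cells only. Of these, 1684 had a bound, with a median of at least 1.78-fold lower in stimulated cells, and 380 were at least 4-fold lower. Among 2789 transcripts with several probes and at least 1 of them 2-fold different, 36 had probes that went both ways by that much. The authors' deposited table for the lymphocytes lists 12855 probes with at least a 2-fold difference, 6498 higher and 6357 lower in stimulated cells by its normalized values.

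**Figure D4:**
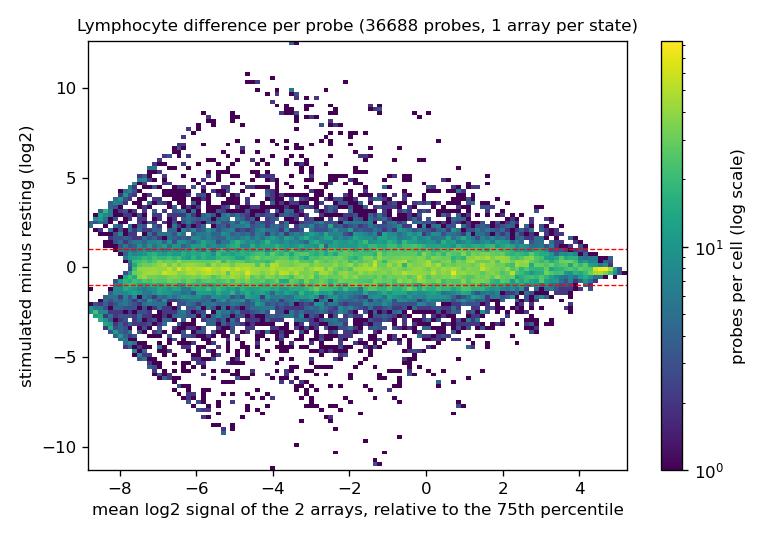
Stimulated minus resting lymphocytes in log2 (vertical axis) against the mean log2 signal of the 2 arrays relative to the 75th percentile (horizontal axis), for 36688 probes, with colour giving probes per cell on a log scale. Dashed lines mark 2-fold differences, outside which lie 5766 higher and 6125 lower probes.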

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

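Girdle against chorion: normexp, the treatment of saturated and non-uniform probes and the count shared by 3 scalings were chosen after the data were seen. The count of 14203 probes stayed within 1.5 times (11806 to 16077) under the quantile, median and normexp settings and both filters on dim probes. It also did so under the trend and robust priors, the slide as a block, the settings for saturated and non-uniform probes, and the 3 scalings together. The authors' deposited table holds 14550 probes at an uncorrected p of at most 0.05, which is an unlike threshold. At an unadjusted p under 0.05 the main limma fit gave 18205. Higher probes rose from 6117 to 9768 with median scaling, through the shift of all differences by 0.23. Without the conceptus as a block the paired design is lost, and 6122 probes passed (2232 higher, 3890 lower), 6096 of them among the 14203. With 1 conceptus left out, which leaves fewer samples, counts were 6054 to 9315 (1898 to 3572 higher, 4156 to 5743 lower). A plain paired t-test gave 3 probes (1 higher, 2 lower) and a plain unpaired one 3999 (1708 higher, 2291 lower), where the spread of each probe is estimated alone. A 2-fold minimum left 9030 (3227 higher), and 1 probe per transcript, with fewer probes tested, 8036 (3404 higher, 4632 lower). None of the 14203 calls passed in the opposite direction in any refit run here. Such a reversal was possible only where signals or samples changed: the quantile, median and normexp settings, capped signals and a conceptus left out. The 4 named transcripts passed in every refit that tested them except the plain paired t-test (adjusted p 0.0595 to 0.0951), and DN508408 also missed in the unpaired one (adjusted p 0.0643). Over all refits their adjusted p ran from 0.000781 to 0.0951, and DN507748 was not tested without saturated probes. Lymphocytes: the counts of 2-fold differences stayed within 1.5 times under every setting run. Probes at least 4-fold lower fell from 2281 to 1516 with normexp (the cause was not tested). They fell to 1482 among probes well above background on both arrays, a smaller set. Probes at least 4-fold higher fell from 2208 to 1507 and 1557 in these settings, a similar fall that stayed within 1.5 times. Gene list tests with their alternatives, which need symbols, and normexp on mean spot signals, for which the median was used, were not run. Signal over background limits the dim probes, 8078 of which were not tested.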

Other observations

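The test of the scaling of the arrays, the test of a trend with brightness and the slope of the brightest unsaturated probes were chosen after the results they bear on were seen. So were the use of probes called under all 3 scalings and of 1 probe per transcript in the lymphocyte comparisons below, which had been set for probes; the other tests were set before.

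Transcripts higher in the girdle were detected more often in blood lymphocytes than transcripts higher in the chorion. Counting 1 probe per transcript among those called in the same direction under all 3 scalings, 94.9% of 3291 girdle-higher and 87.6% of 3207 chorion-higher transcripts were well above background on at least 1 lymphocyte array. Within 10 strata of placental brightness the odds ratio was 2.19 (95% interval 1.80 to 2.66, over transcripts, which are not independent). The strata matched the signal of the brighter tissue and not the size of the difference. Among probes called under all 3 scalings, 2214 were at least 4-fold lower and 1223 at least 4-fold higher in the girdle. The odds ratio therefore cannot tell the direction of a difference from its size. Over all probes past the threshold with the 75th percentile it was 1.61 (95% interval 1.41 to 1.83). Of the tested probes that did not pass the threshold between the tissues, 97.4% were detected there. The lymphocytes came from 1 mare.

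The differences between girdle and chorion also ran with those between stimulated and resting lymphocytes. Over 19421 transcripts measured in both comparisons, 838 were higher in girdle and at least 2-fold higher in stimulated cells, against 431 for independent lists, and 727 were lower in both, against 396. In opposite directions, 300 were higher in girdle and lower in stimulated cells, against 441, and 366 were lower in girdle and higher in stimulated cells, against 387. The Spearman correlation of the differences was 0.225 across transcripts, 0.215 across 33349 probes, 0.202 with quantile normalization and 0.167 to 0.245 for single conceptuses. Both comparisons came from different arrays and share no control. A trend with brightness in both differences is argued against: centring each difference within 20 bins of mean signal left a correlation of 0.214. The 95% interval was 0.201 to 0.227 over transcripts, which are not independent, and covers no spread between conceptuses or arrays. In single bins the correlation was 0.109 to 0.299. A set of transcripts that moves alike in the girdle and in stimulated lymphocytes may therefore exist, as a hypothesis that rests on 1 array per lymphocyte state and on transcripts without gene names.

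For the probes past the threshold between girdle and chorion, the test of a difference between slides cannot decide. Both tissues of each conceptus shared a slide, so a shift between slides cancels within the conceptus. What the values show is that direction carried over. Of the 6054 probes called on the slide of conceptuses 3637 and 3961, 97.8% had the same direction in conceptus 3879, against 82.0% of all probes tested in that fit. Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many probes as the real one (14203, the real split itself), and the highest of the others gave 0 with limma. The splits are too few for a share under 0.05. In the others the tissue difference enters the spread, so that few calls follow by construction and they give no measure of chance: at an unadjusted p under 0.05 there were 116 to 168 probes in the 3 that part all 3 conceptuses, as the real split does, and 408 to 969 in the 6 that part 1. The tissue itself stays open as the source.

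Over all calls, the excess of lower over higher probes with the 75th percentile may come from the scaling. The share lower was 56.9% there, 45.1% under quantile normalization and 39.2% under median scaling. Among probes called in the same direction and that large under every scaling, 4446 were at least 2-fold lower and 3178 at least 2-fold higher. At 4-fold the counts were 2214 lower and 1223 higher. At 16-fold they went the other way, with 192 lower and 265 higher. For probes of at least 2-fold or 4-fold, these counts argue against the scaling as the only source of the excess. No biological explanation for the split was tested, and which scaling is right cannot be read from these arrays.

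The difference on the slide with the lower scanner ceiling was set against that of conceptus 3879. The slope was 0.65 for probes with a saturated spot and 0.84 for unsaturated probes. It was 0.19 smaller for the saturated ones (95% interval 0.168 to 0.213, over probes, which are not independent). Against the 4040 brightest unsaturated probes (slope 0.81) it was 0.157 smaller (95% interval 0.127 to 0.187). In the authors' deposited table for the lymphocytes, the direction word reads down for 22103 probes whose normalized value is higher in stimulated cells and up for 21481 whose value is lower, so directions here were taken from the values. In the authors' deposited table for girdle and chorion, the direction word opposes the raw columns for 69 probes.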
